A study of Mus musculus with 8 samples.

How the data were processed

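RNA bound to ribosomes of Müller cells was measured by RNA-seq in 8 mouse retina samples at postnatal day 14 of oxygen-induced retinopathy. The groups were 4 wild-type (WT) samples and 4 with a Müller cell-specific conditional knockout of Nrf2 (cKO), numbered 1, 3, 4 and 5 in each group. Per the labels, RNA was extracted with the RNeasy Micro kit, and directional libraries were made from poly(A)-selected RNA with NEBNext kits. The labels give no sex, litter, batch, Cre driver or deleted exon, and do not say whether each sample was 1 animal, so the p-values measure the spread between these samples.

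The authors deposited 1 table of FPKM (fragments scaled to the length of the transcript and to the fragments of the library), with 12339 genes and 1 column per library. The name of the table gives the unit, and the values were not whole numbers and had unequal column sums. The submitters' processing notes list STAR, edgeR, GRCm38 and mm10 without a version or a role. The counting tool, its annotation and strand setting, and the gene filter are not stated. Each deposited gene had a mean FPKM above 2 over the 8 libraries, so genes below that level could not be examined. Of the 12339 gene IDs, 12327 were found in GENCODE mouse release 21 on GRCm38, and 99.6% of these had the same symbol. Coordinates and gene classes were taken from that annotation, since the position given for a gene in the deposited table was often the span of several overlapping genes. The FPKM of a library summed to between 410581 and 448130, with medians between 14.6 and 15.8. The number of fragments per library is not given, and no counting interval or floor was computed.

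Values were taken as log2(FPKM + 0.5) without further scaling. Differences are cKO minus WT. The cKO and WT libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), in a two-sided test with Benjamini-Hochberg adjustment over 12339 genes and a threshold of 0.05. The same replicate numbers occurred in both groups, so a rule was set for testing whether they pair the samples. After each group's mean was removed, the correlation across genes between a WT and a cKO library was 0.261 to 0.591 for equal numbers and −0.479 to 0.211 for unequal ones. Each of the 8 libraries correlated best with the library of its own number. By the rule the numbers paired the samples, and a second fit with the replicate number as a block is given beside the first. It left 3 residual degrees of freedom instead of 6.

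The lists of genes, the tests, the threshold, the rule for named genes and the first set of other settings were fixed before the data were examined. The lists held 720 distinct genes, of which 488 were measured, 4 of them matched by gene ID or synonym. Lists with at least 5 measured members were tested with camera from limma, which compares a list with the other genes, at a preset correlation of 0.01. Adjustment was over the 24 process lists and, separately, over the 7 cell type marker lists. Camera was repeated with a correlation estimated for each list, and fry from limma was run to test whether the members of a list moved, on balance, one way. Members were counted after adjustment over all genes and adjusted over the list alone. For Nfe2l2 an exact two-sided permutation test of the group labels was used, for which 70 assignments allow no p below 0.0286.

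Named genes followed a rule. Nfe2l2, Keap1 and Rpl22 were always named. In each direction the rule took up to 12 genes with the largest change past the threshold whose cKO values lay beyond those of all WT libraries. Names of clones and genes without a symbol were left out. Where fewer than 5 genes passed in a direction, it took the 5 with the smallest p instead, as values. It also took up to 4 members with the smallest p of each list with at least 3 measured members, or up to 6 in the Nrf2, HIF and angiogenic lists. Vegfa, Hmox1, Nqo1, Gclm, Slc7a11 and Gfap were added where measured. The 12 highest and 12 lowest genes of the fit with the block were taken by the same rule, after the fit had been seen. Some genes that the rule took are not reported here.

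Other settings fixed in advance were a pseudocount of 0.1 or 1, no filter or a minimum mean FPKM of 2, median-of-ratios, equal-sum (TPM) or quantile scaling, the replicate block, library weights, eBayes without a trend or robust, a threshold of 0.1, and leaving out each library in turn. The planned minimum means, 0.5 and 2, removed no gene. Settings added after the data were seen were a minimum mean FPKM of 5, a correction per library for transcript length and GC content (splines with 4 degrees of freedom), a covariate for unspliced RNA, the FPKM of Xist as a covariate, the 6 libraries with Xist alone, and the block with these and other settings or without 1 pair. The covariate for unspliced RNA was the mean log2 value of 81 genes annotated as TEC, a class of transcripts still to be checked by experiment, or sense intronic. On simulated data made from the libraries with 200 changed genes, the fit without the block found 91% of changes of 1 and 96% of changes of 2 (log2), with 6.86% false calls. The fit with the block found 97% and 100%, with 4.98% false calls. The noise was drawn independently for each gene, so these rates may not hold for correlated genes or for smaller changes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.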

Results

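RNA on the ribosomes of Müller cells, the main glia of the retina, was sequenced from 8 mouse retina samples in oxygen-induced retinopathy. In this model, pups kept in high oxygen are returned to room air, after which the inner retina is short of oxygen and new vessels grow. RiboTag puts a tag on the ribosomal protein Rpl22 in cells that express Cre, so that the ribosomes of those cells can be pulled down with their RNA. There were 4 WT libraries and 4 cKO libraries, all from postnatal day 14. FPKM of 12339 genes summed to between 410581 and 448130 per library, and between 2 and 11 genes per library were at 0. The Müller cell genes Glul (3875 ± 825 FPKM in WT and 3150 ± 840 in cKO; SD, n = 4 each) and Rlbp1 (1462 ± 286 and 1325 ± 168) were abundant. These 2 genes were chosen after their values were seen. Markers of rods and bipolar cells were abundant too, so the values were not of Müller cells alone.

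The comparison asked which RNAs on Müller cell ribosomes differed when Nrf2, a transcription factor that activates antioxidant and detoxification genes, was deleted in these cells. Nfe2l2, the gene of Nrf2 (ENSMUSG00000015839; GRCm38 chromosome 2, 75675513 to 75704641, minus strand), was at 19.2 ± 2.66 FPKM in WT and 13.6 ± 2.66 in cKO (SD, n = 4 each). The difference was −0.50 on the log2 scale (SE 0.15), or 29.1% lower, and each cKO value lay below each WT value (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). The adjusted p over all genes was 0.453 without the replicate block and 0.0219 with it. With the block, leaving out pair 1, 4 or 5 gave 0.0785, 0.0846 and 0.0634, and leaving out pair 3 gave 0.0182. The value covers the whole gene, and the deleted exon is not stated, so RNA from the remaining exons is part of it. RNA of other retinal cells, in which the gene was not targeted, may be part of it too. Keap1, which targets Nrf2 for degradation, was at 24.1 ± 3.38 and 24.7 ± 1.93 FPKM (adjusted p = 0.898, and 0.732 with the block). Rpl22 was at 152 ± 15.1 and 163 ± 15.9 FPKM (adjusted p = 0.709, and 0.329 with the block).

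Without the block, 0 of 12339 genes passed the threshold in limma, and the smallest adjusted p was 0.149. At an unadjusted p under 0.05 there were 1310 genes, 487 higher and 823 lower in cKO. Leaving out 1 library moved this count between 609 (without WT 3) and 2227 (without cKO 3), and library weights gave 3374. With the block, 1305 genes passed, of which 369 rose and 936 fell, and 3503 had an unadjusted p under 0.05. Of the 1305, 34 rose and 347 fell by at least 1.5-fold. Leaving out 1 pair left 402 genes without pair 1, 606 without pair 3, 524 without pair 4 and 821 without pair 5. Of the 1305, 324 passed in each of these 4 fits, 27 of them higher and 297 lower. These 324 are called lasting below, and the adjusted p of a single gene is that of the fit with the block unless stated. All cKO values lay above or below all WT values in 535 genes, which is 4.34% where chance gives 2.86%. Within the pairs, 4463 genes (36.2%) differed in the same direction in all 4, 2060 higher and 2403 lower, where chance gives 12.5%. Both chance shares are averages. Genes that move together can take a share far from them, and neither excess was tested.

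Of the genes with the smallest p without the block, 5 higher and 4 lower ones are given here. These had no overlap between the groups, and each was lasting with the block. On the higher side they were Rgs5, Smtnl2, Esr1, Kcne2 and Hk2. Rgs5, a regulator of G protein signalling known from pericytes (ENSMUSG00000026678; GRCm38 chromosome 1, 169655501 to 169695813), was at 28.0 ± 2.25 FPKM in WT and 47.9 ± 5.52 in cKO (log2 difference 0.76, SE 0.11, adjusted p = 0.149, and 0.00277 with the block). Esr1, the estrogen receptor alpha, rose from 14.3 ± 3.58 to 26.7 ± 2.78 FPKM (0.91, adjusted p = 0.00242). Kcne2, a potassium channel subunit, rose from 36.5 ± 5.64 to 60.9 ± 7.80 (0.74, adjusted p = 0.00920). Smtnl2 differed by 0.90 (0.00509) and Hk2, a hexokinase of glycolysis, by 0.61 (0.0141). On the lower side, Ptprk, a receptor tyrosine phosphatase, fell from 16.3 ± 4.56 to 7.29 ± 1.46 FPKM (−1.09, adjusted p = 0.00275), and Gabbr1, a subunit of the GABA-B receptor, from 84.6 ± 7.51 to 55.7 ± 1.01 (−0.59, adjusted p = 0.00288). mt-Nd1 (−0.66, adjusted p = 0.00412) and Galnt17 (−0.74, adjusted p = 0.00417) were also among them.

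Among genes that passed with the block, had no overlap between the groups and bore no clone name, the largest rises were in Lcn2, Serpina3n, C4b, Hk1os, Esr1 and Smtnl2, followed by Cks2, Klhl14, Rgs5, Eif4ebp1, Piwil4 and Kcne2. Complement C4b rose by 1.18 (adjusted p = 0.0225) and Eif4ebp1, a repressor of translation initiation, by 0.76 (0.0242), and neither was lasting. Among the largest falls of such genes were Ints6l (−1.39, adjusted p = 0.00191), Cldn7 (−1.16, adjusted p = 0.00930) and Ptprk. They were followed by Efcab7, Tspan10, Ttll3, Herc2, Erich3, Nemp2, Zscan18 and Glp2r, which differed by −0.99 to −0.80. Herc2, a ubiquitin ligase, fell from 41.1 ± 4.99 to 22.7 ± 6.45 FPKM (−0.88, adjusted p = 0.00626) and was lasting, as were Ints6l, Efcab7, Ttll3, Nemp2 and Zscan18.

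**Figure D1:**
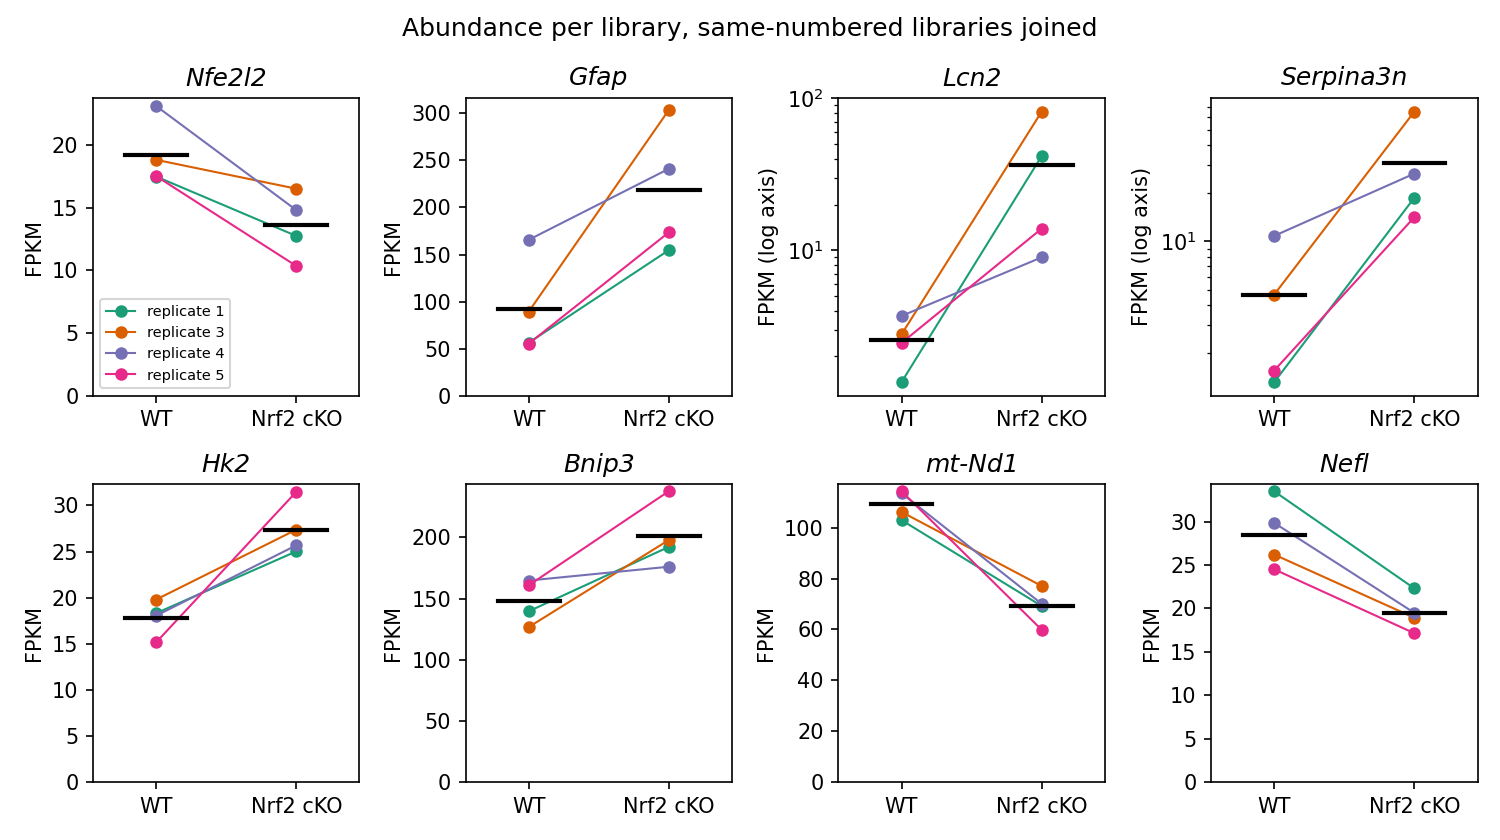
FPKM of 8 genes in each library (points, with lines joining WT and cKO libraries of the same number; black bars are group means; Lcn2 and Serpina3n on log axes). Nfe2l2 lay between 17.5 and 23.1 FPKM in WT and between 10.4 and 16.5 in cKO.

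The 4 lists of known Nrf2 targets did not pass the test. Of the fixed genes, 17 of 34 detoxification and export targets were measured. So were 13 of 15 glutathione and thioredoxin, 7 of 7 NADPH supply and 8 of 10 heme and iron targets. The rest could not be examined. The glutathione and thioredoxin targets (13 genes) differed by a mean of 0.06 (log2, adjusted p = 0.358), the detoxification and export targets (17 genes) by 0.03 (0.438), the NADPH supply targets (7 genes) by 0.05 (0.363), and the heme and iron targets (8 genes) by 0.14 (0.124). Of these 45 members, Sesn2, a stress-induced sestrin, was the only one past the threshold with the block (0.32, adjusted p = 0.0451), and 0 passed adjusted over the list alone. Sesn2 was not lasting. Nqo1, the quinone reductase used as an Nrf2 readout, was at 5.84 ± 1.68 FPKM in WT and 5.004 ± 0.544 in cKO (adjusted p = 0.492). Hmox1, heme oxygenase, was at 4.32 ± 1.82 and 5.61 ± 1.54 (0.255), and Gclm, of glutathione synthesis, at 24.4 ± 2.17 and 26.1 ± 0.748 (0.446). Slc7a11, the cystine carrier, was not in the table. Among 8 Nrf2 regulator genes (mean 0.04, adjusted p = 0.385), Nfe2l2 and its partner Mafg (−0.39, adjusted p = 0.0296) fell with the block and 6 did not pass, and the same 2 passed adjusted over the list alone. Mafg was not lasting. The heme and iron list was at 0.08 without WT 1 (adjusted p = 0.409), and passed without WT 4 (0.20, adjusted p = 0.0316) and with library weights (0.23, adjusted p = 0.0312). Leaving out 1 library moved the glutathione and thioredoxin list between 0.03 (without WT 3) and 0.10 (without WT 4), never past the threshold.

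The hypoxia response was higher in cKO as a list, while most of its members did not pass. The 30 measured genes of the HIF list, which are switched on in low oxygen, differed by a mean of 0.24 (adjusted p = 3.16e-07, but adjusted p = 0.377 with an estimated correlation). With the block 7 rose, 0 fell and 23 did not pass. Adjusted over the list alone, 14 passed with the block, 13 of them higher, and 4 without it. Hk2 rose from 17.8 ± 1.94 to 27.4 ± 2.90 FPKM, Slc16a3, a lactate exporter, from 64.5 ± 3.55 to 88.6 ± 13.98 (0.44, adjusted p = 0.0171), and Egln1, an oxygen sensor, from 40.7 ± 5.13 to 54.5 ± 6.59 (0.42, adjusted p = 0.0141). Of these, Hk2 was lasting. The list mean differed by 0.29, 0.40, 0.00 and 0.27 in pairs 1, 3, 4 and 5. The glycolysis list (17 genes) differed by a mean of 0.15 (adjusted p = 0.00271, but adjusted p = 0.550 with an estimated correlation), with Hk2 and Pgam1 (0.38, adjusted p = 0.0146) past the threshold with the block and 15 not. Adjusted over the list alone, 5 passed, all higher. Hk2, Pfkl, Aldoa, Tpi1, Gapdh, Pgk1, Eno1 and Ldha are in both the glycolysis and the HIF list, so these lists are not independent. With quantile scaling the glycolysis list did not pass (mean 0.06, adjusted p = 0.297).

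Vegfa, the main vessel growth factor of this model, was at 221 ± 33.7 FPKM in WT and 207 ± 36.8 in cKO (−0.10, adjusted p = 0.407), a difference within the spread between libraries. The list of secreted pro-angiogenic factors (14 genes) nevertheless differed by a mean of 0.30 (adjusted p = 0.00123, but adjusted p = 0.550 with an estimated correlation). With the block Fgf2 rose (0.50, adjusted p = 0.0467), without being lasting, and 13 did not pass, and adjusted over the list alone 4 passed, all higher. Pgf was at 2.35 ± 0.745 and 4.001 ± 1.77 FPKM (adjusted p = 0.124) and Vegfb at 16.8 ± 2.48 and 22.8 ± 4.32 (0.0624). Vegfa and Adm are members of the HIF list too. Secreted anti-angiogenic and guidance factors (14 genes) differed by −0.06 (adjusted p = 0.557). Slit2, a guidance factor, fell with the block (−0.46, adjusted p = 0.00888), was lasting, and passed adjusted over the list alone as the only member. The list means of WT 4 stood above those of the other WT libraries, at 6.53 against 6.22 to 6.27 (log2) for the HIF list and 4.01 against 3.39 to 3.48 for the pro-angiogenic list.

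The reactive gliosis list had the largest mean difference of the 31 tested lists. The 23 genes differed by a mean of 0.71 (adjusted p = 1.79e-06, but adjusted p = 0.550 with an estimated correlation). With the block 9 rose, 0 fell and 14 did not pass. Adjusted over the list alone, 12 passed with the block and 4 without it, all higher. Lcn2, lipocalin 2 (ENSMUSG00000026822; GRCm38 chromosome 2, 32384633 to 32388252), rose from 2.57 ± 0.967 FPKM to 36.6 ± 33.5 (3.15, SE 0.53, adjusted p = 0.0120, and 0.0589 without pair 1). Serpina3n, a protease inhibitor of reactive astrocytes, rose from 4.59 ± 4.44 to 31.2 ± 23.2 (2.80, adjusted p = 0.00383), and Gfap, the filament protein of reactive glia, from 91.7 ± 51.8 to 218 ± 68.0 (1.35, adjusted p = 0.00521), and both were lasting. Complement C3 was at 1.93 ± 0.531 and 3.97 ± 1.24 (adjusted p = 0.0605). Reads of Serpina3n can be shared with its near-identical neighbours. The list mean differed by 0.88, 1.15, 0.20 and 0.59 in pairs 1, 3, 4 and 5.

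The 32 genes of Müller cell identity differed by a mean of −0.06 (adjusted p = 0.358). Of them 3 fell with the block, also adjusted over the list alone, and 29 did not pass. Aqp4, the water channel of glial endfeet, fell from 49.0 ± 9.62 to 38.3 ± 7.99 FPKM (−0.35, adjusted p = 0.0346) and was not lasting. Abca8a (−0.36, adjusted p = 0.0418), named after its values were seen, was also among the 3. The Müller cell list passed, as lower, without WT 1 (−0.16, adjusted p = 0.00148) and without cKO 4 (−0.15, adjusted p = 0.00192), and also with quantile scaling (−0.11, adjusted p = 0.00200), with the covariate for unspliced RNA (−0.15, adjusted p = 8.64e-04) and in the libraries with Xist alone (−0.15, adjusted p = 3.22e-04). Astrocyte markers (8 genes, with Gfap among them) differed by a mean of 0.33 (adjusted p = 0.00878, but adjusted p = 0.391 with an estimated correlation). With the block Gfap and S100b (0.44, adjusted p = 0.0467) rose and 6 did not pass, and adjusted over the list alone 3 passed. The astrocyte list did not pass without WT 1 (0.22, adjusted p = 0.0657), without cKO 4 (0.24, adjusted p = 0.0916) or with the covariate for unspliced RNA (0.26, adjusted p = 0.0642). Inflammatory cytokine and NF-kB genes (8 genes, mean 0.06, adjusted p = 0.404) included Nfkbia, the inhibitor of NF-kB, which rose with the block (0.39, adjusted p = 0.0302) but was not lasting. Adjusted over the list alone, 2 passed, 1 in each direction. The interferon response genes (21) differed by 0.12 (adjusted p = 0.286), with 0 past the threshold with the block or adjusted over the list alone. The interferon list passed, as higher, without WT 3 (0.31, adjusted p = 0.00131), WT 4 (0.31, adjusted p = 0.00873) or cKO 5 (0.28, adjusted p = 0.00310), with the unspliced-RNA covariate (0.35, adjusted p = 2.92e-04) and in the libraries with Xist alone (0.20, adjusted p = 0.0248). The NF-kB list also passed in the last 2 of these fits (0.18 in each, adjusted p = 0.0218 and 0.0348).

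Stress and signalling lists were higher by small amounts. The ATF4 and amino acid response (20 genes) differed by a mean of 0.21 (adjusted p = 0.00526, but adjusted p = 0.609 with an estimated correlation), with 4 higher with the block and adjusted over the list alone, and 16 not passing. Atf4 rose from 87.2 ± 5.17 to 105 ± 7.64 FPKM (0.27, adjusted p = 0.0256), Atf5 by 0.46 (0.0307) and Ddit3 by 0.41 (0.0355), none of them lasting. The other, Nupr1 (1.01, adjusted p = 0.0494), was named after its values were seen. Without cKO 3 the ATF4 list did not pass (0.09, adjusted p = 0.294). ER chaperones (19 genes) differed by a mean of 0.15 (adjusted p = 1.03e-04, but adjusted p = 0.377 with an estimated correlation), with 1 member higher with the block, 18 not passing and 0 adjusted over the list alone. That member was Manf (0.29, adjusted p = 0.0378), named after its values were seen. Hspa5, the main ER chaperone, was at 209 ± 17.4 and 255 ± 17.1 FPKM (adjusted p = 0.0774). Immediate early genes (13) differed by a mean of 0.25 (adjusted p = 0.00139, but adjusted p = 0.550 with an estimated correlation). Btg2 (0.30, adjusted p = 0.0216) rose with the block and adjusted over the list alone, was not lasting, and 12 members did not pass. The mean of the immediate early genes was 0.41 without WT 4. Cytosolic heat shock genes (11) differed by 0.11 (adjusted p = 0.0595, and 0.0410 with the block, but 0.605 with the block and an estimated correlation), with 0 members past the threshold either way. The heat shock list passed without WT 4 (0.15, adjusted p = 0.0296), without cKO 1 (0.13, adjusted p = 0.0475), with TPM scaling (0.08, adjusted p = 0.0437) and with the length and GC correction (0.11, adjusted p = 0.0256).

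The list of RNAs encoded in the mitochondrial genome was lower in cKO and that of the nuclear-encoded respiratory chain higher, with most members of the latter not passing. The 7 mitochondrially encoded genes differed by a mean of −0.51 (adjusted p = 7.03e-08, but adjusted p = 0.377 with an estimated correlation), by −0.51, −0.38, −0.63 and −0.51 in pairs 1, 3, 4 and 5. All 7 fell with the block, and all 7 passed adjusted over the list alone in both fits. Whether these 7 RNAs were on the tagged ribosomes was not tested, so their fall is not read here as one of ribosome-bound RNA. mt-Nd1 fell from 109 ± 5.58 to 69.0 ± 7.09 FPKM and mt-Nd2 from 60.3 ± 6.64 to 40.9 ± 3.65 (−0.55, adjusted p = 0.00279), and both were lasting. The 41 nuclear-encoded genes differed by a mean of 0.16 (adjusted p = 4.06e-05, but adjusted p = 0.625 with an estimated correlation), with 7 higher with the block, 14 adjusted over the list alone and 34 not passing. Sdhc rose by 0.26 (0.0302) and Ndufb8 by 0.33 (0.0338), and neither was lasting. Cytosolic ribosomal protein genes (37) differed by a mean of 0.20 (adjusted p = 1.79e-06, but adjusted p = 0.625 with an estimated correlation), with 5 higher with the block, among them Rpl18 (0.31, adjusted p = 0.0319, not lasting), 12 adjusted over the list alone and 32 not passing. Also among the 5 were Rpl23, Rpl37 and Rps20, which were named after their values were seen. Without WT 3 the mean of the nuclear-encoded respiratory chain was 0.08 and that of the ribosomal proteins 0.09, and without cKO 3 the former was 0.25. Reads of mitochondrial and ribosomal protein genes can be shared with near-identical copies elsewhere in the genome.

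Genes annotated as TEC or sense intronic had a lower median in cKO. They were taken to stand for unspliced and nuclear RNA, which was not tested. Their median difference was −0.29 over 81 genes, against 0.006 over 11517 protein-coding genes, and 26 of the 81 fell with the block, 0 rose and 55 did not pass. No test of the class as a set was run, and the median of the 9 sense intronic genes was 0.009 in pair 5. The score made from them was 2.41 ± 0.335 in WT and 2.04 ± 0.367 in cKO (log2; SD, n = 4; exact permutation p = 0.2), and lower in cKO by −0.38, −0.29, −0.41 and −0.36 in the 4 pairs. With the score as a covariate, the respiratory chain list differed by −0.02 (adjusted p = 0.392) and the ribosomal protein list by −0.01 (adjusted p = 0.929). The covariate also moved the mitochondrially encoded list to −0.33 (adjusted p = 1.61e-08), the amacrine list to −0.20 (0.0128) and the glycolysis list to 0.08 (0.0218). Across genes, which are not independent replicates, the difference had a Spearman correlation of −0.33 with transcript length. The median difference was 0.11 for genes with transcripts of up to 1904 nt and −0.11 for those of 5325 nt or more. In the 6 libraries with Xist alone, the respiratory chain list differed by 0.05 (adjusted p = 0.224), the ribosomal protein list by 0.08 (0.0290) and the amacrine list by −0.23 (0.00698). With Xist FPKM as a covariate over all 8 libraries, the respiratory chain list differed by −0.10 (adjusted p = 6.34e-05) and the ribosomal protein list by −0.09 (9.74e-04), both now past the threshold on the lower side. The mitochondrially encoded list was at −0.27 (1.31e-05), and the glycolysis (0.06, adjusted p = 0.168), amacrine (−0.14, 0.147) and astrocyte (0.22, 0.302) lists did not pass. Lists that passed only with this or some other settings were Müller cell identity (−0.20, adjusted p = 1.31e-05), interferon (0.40, 1.64e-04), NF-kB (0.19, 0.0250), cholesterol (0.19, 1.64e-04) and the matrix (0.23, 0.0363).

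**Figure D2:**
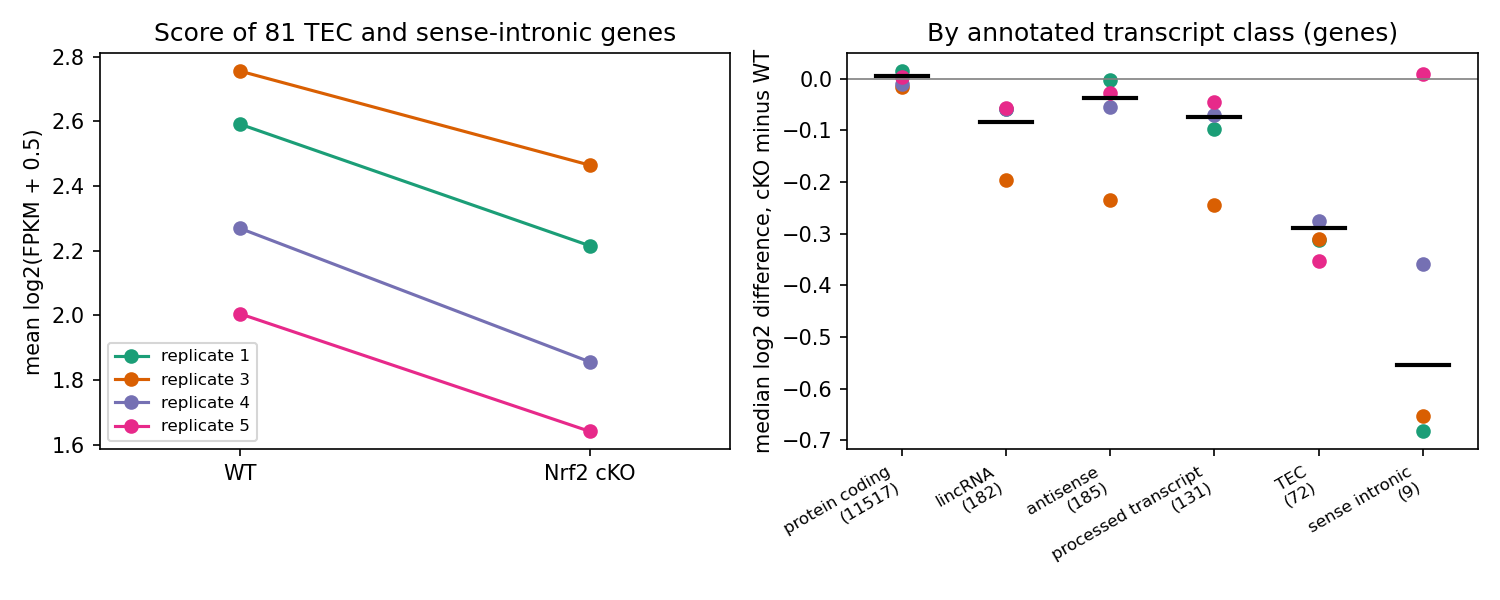
Left, unspliced-RNA score of each library (mean log2(FPKM + 0.5) of 81 genes; lines join libraries of the same number); right, median log2 difference (cKO minus WT) by annotated class, with points for the 4 pairs in the same colours and black bars for all libraries. The score was lower in cKO in each pair, and the TEC median lay at −0.29.

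Markers of other retinal cells moved in different directions. The mean of the rod list was 7.75 to 8.32 (log2) over the libraries, beside 7.48 to 8.12 for Müller cell identity. These lists were fixed because pull-downs can carry RNA of other retinal cells. A difference in them may be one in the share of that RNA, which was not tested. Bipolar cell markers (13 genes) differed by a mean of 0.31 (adjusted p = 1.50e-05, but adjusted p = 0.207 with an estimated correlation), with 8 higher with the block, 10 adjusted over the list alone and 5 not passing. Pcp2 rose from 742 ± 110 to 1053 ± 125 FPKM (0.51, adjusted p = 0.00624) and Car8 from 53.7 ± 5.42 to 77.0 ± 8.99 (0.51, adjusted p = 0.00820), both lasting. Amacrine cell markers (8 genes) differed by a mean of −0.39 (adjusted p = 4.06e-04, but adjusted p = 0.207 with an estimated correlation), with 4 lower with the block, 6 adjusted over the list alone and 4 not passing. Tfap2b differed by −0.63 (0.00794) and Gad1 by −0.46 (0.0350). The others were Tfap2a and, named after its values were seen, Calb2. Retinal ganglion cell markers (9 genes) differed by a mean of −0.35 (adjusted p = 4.06e-04, but adjusted p = 0.207 with an estimated correlation), with 4 lower with the block, 7 adjusted over the list alone and 5 not passing. The neurofilament gene Nefl fell from 28.5 ± 3.999 to 19.5 ± 2.14 FPKM (−0.54, adjusted p = 0.00381) and Nefm from 16.8 ± 2.46 to 10.9 ± 2.18 (−0.61, adjusted p = 0.00446), both lasting, and the others were Nefh and Sncg. Rod markers (17 genes) differed by 0.07 (adjusted p = 0.549), and by −0.02 with quantile scaling. Of the rod markers 1 passed with the block (Gngt1, 0.39, adjusted p = 0.0432), 3 adjusted over the list alone and 16 did not pass. The rod list passed, as higher, without WT 1 (0.16, adjusted p = 0.0287) and without cKO 3 (0.17, adjusted p = 0.0405).

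Cone markers (10 genes) differed by −0.14 (adjusted p = 0.754), with 4 lower and 1 higher with the block, 6 past the threshold adjusted over the list alone and 5 not passing. The short-wave opsin Opn1sw fell from 19.4 ± 4.60 to 12.5 ± 3.05 FPKM (−0.62, adjusted p = 0.00440), while Gngt2, a cone transducin subunit, rose from 32.0 ± 5.49 to 44.96 ± 8.91 (0.48, adjusted p = 0.00662), both lasting. The other lower cone genes were Opn1mw and, named after their values were seen, Pde6c and Arr3. Endothelial markers (5 genes) differed by 0.04 (adjusted p = 0.847), a difference that camera put on the lower side with quantile scaling, with 0 past the threshold with the block or adjusted over the list alone. Of the 24 process lists 10 passed, and of the 7 marker lists 4. With an estimated correlation 0 and 0 passed, and fry called 0 and 0. With the block 11 and 4 passed, and 0 and 0 of these with an estimated correlation. With the block fry called 1 process list, the mitochondrially encoded one (adjusted p = 0.0299), and 3 marker lists, those of bipolar (0.0449), amacrine (0.0143) and ganglion cells (0.0177).

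**Figure D3:**
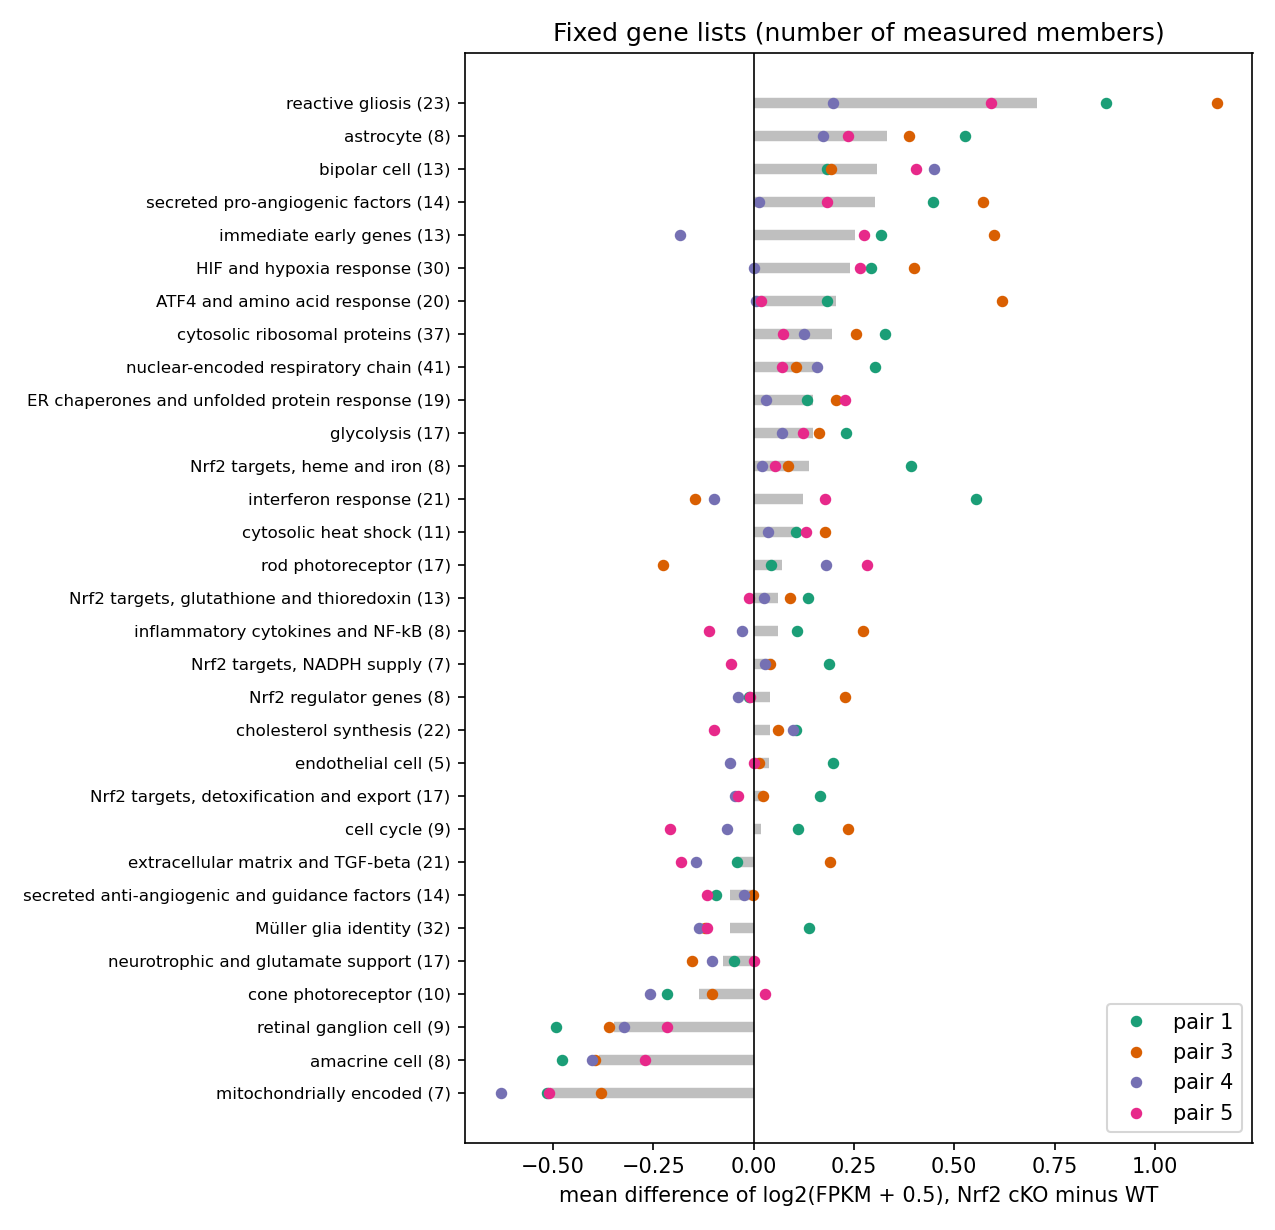
Mean log2 difference (cKO minus WT) of each tested list, as grey bars over all libraries and coloured points for the 4 pairs, with the number of measured members in brackets. The reactive gliosis list differed by 0.71 and the mitochondrially encoded list by −0.51.

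The remaining lists did not pass. Cholesterol synthesis genes (22) differed by 0.04 (adjusted p = 0.358), with 0 members past the threshold with the block or adjusted over the list alone, and the cholesterol list passed without WT 3 (0.12, adjusted p = 0.00668), with the unspliced-RNA covariate (0.13, adjusted p = 0.00365) and in the libraries with Xist alone (0.12, adjusted p = 0.0176). Extracellular matrix and TGF-beta genes (21) differed by −0.04 (adjusted p = 0.358). Col6a1 (−0.81, adjusted p = 0.00979) and Col18a1 (−0.30, adjusted p = 0.0399) fell with the block, Timp1, an inhibitor of matrix proteases, rose (1.74, adjusted p = 0.0479), and 18 did not pass, with 4 past the threshold adjusted over the list alone. None of these 3 was lasting. Cell cycle genes (9) differed by 0.02 (adjusted p = 0.358), with Ccna2, a cyclin of dividing cells, lower with the block (−1.10, adjusted p = 0.00930), lasting, and the only member adjusted over the list alone. Neurotrophic and glutamate support genes (17) differed by −0.08 (adjusted p = 0.358), with Fgf2 higher and Aqp4 lower with the block, 15 not passing, and 5 past the threshold adjusted over the list alone. The neurotrophic list passed, as lower, in the libraries with Xist alone (−0.13, adjusted p = 0.0190). Leaving out 1 library moved its mean between −0.03 (without WT 4) and −0.12 (without cKO 4), never past the threshold.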

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

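For the tests of unspliced RNA on the lower genes, of sex and of astrocyte RNA, the prediction was written after the outcome of the test was seen. For the others it was written before. The covariates and the length and GC correction that some of these tests used were added after the data were seen.

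With the replicate block 936 genes were lower and 369 higher in cKO. After correction for transcript length and GC, 67.7% of the lower genes (634 of 936) were still called lower. This argues against a length or GC trend as the whole cause of the fall. Of the 369 higher genes, 166 were still called higher. Without the block, the correction moved the respiratory chain list from 0.16 to 0.07 and the ribosomal protein list from 0.20 to 0.11. A length or GC trend may thus account for part of the rises. Less unspliced and nuclear RNA in the cKO pull-downs may account for part of the fall, since the median of the TEC and sense intronic genes differed by −0.30 from that of protein-coding genes and was lower in each of the 4 pairs. That these genes report such RNA was not tested. Unequal sex of the animals may account for part too, since with Xist FPKM as a covariate the median of the 936 genes went from −0.50 to −0.086 (log2). Xist is a nuclear RNA itself and would fall with less of it, so these 2 explanations are not separated here. Xist was at 0.0863 and 0.00505 FPKM in cKO 4 and 5, and at 27.0 to 72.1 in the WT libraries. By this gene the groups were thus unequal in sex. But Xist also differed by −33.1 and −22.1 FPKM in pairs 1 and 3. As a covariate it thus does not measure sex alone. With the block and the 6 libraries with Xist alone, 580 genes were lower, and their overlap with the 936 is not given. WT 4 and 5 have no partner in that fit, so its difference rests on pairs 1 and 3. A change made by the loss of Nrf2 in the cells stays open, since the score of unspliced RNA and the genotype moved together in every pair.

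The reactive gliosis list was higher in cKO by 0.71. With the unspliced-RNA score as a covariate its mean was 0.86 and it stayed past the threshold. If the slope within the groups also holds between them, this argues against less unspliced RNA, as this score measures it, as the cause. The score was lower in cKO in every pair, so that condition was not tested. With Xist FPKM as a covariate, which moved other lists, the gliosis list was at 0.93 and stayed past the threshold (adjusted p = 6.18e-10). In the 6 libraries with Xist alone it was at 0.85 (camera adjusted p = 2.13e-11). That fit kept cKO 1 and 3, whose pairs differed by 0.88 and 1.15, against 0.20 and 0.59 in pairs 4 and 5. The list thus also differed between libraries that all held Xist, which argues against the mere presence of Xist as the whole cause. Xist was lower in cKO 1 and 3 than in WT 1 and 3. It does not measure sex alone, so these fits do not exclude unequal sex. More astrocyte RNA in the cKO pull-downs could not be excluded: the median astrocyte marker other than Gfap differed by 0.15, against 1.35 for Gfap, but Müller cells express most of these markers. The most abundant of them, Aldoc, was at 454 FPKM in WT and 463 in cKO, Igfbp2 at 48.8 and 60.0, and Agt at 37.1 and 32.9, and of the 8 markers Gfap is also in the gliosis list and Aldoc in the glycolysis list. A stronger glial reaction in cKO is an untested hypothesis that stays open beside it, with a call that rests on the preset correlation (adjusted p = 0.550 with an estimated correlation).

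The HIF list was higher in cKO by 0.24, and by 0.00 in pair 4, with a call that rests on the preset correlation (adjusted p = 0.377 with an estimated correlation). With the unspliced-RNA score as a covariate its mean was 0.25 and it stayed past the threshold. Under the same untested condition on the slope, this argues against less unspliced RNA, as this score measures it, as the cause. With Xist FPKM as a covariate the HIF list was at 0.25 too and stayed past the threshold (adjusted p = 1.59e-07). In the 6 libraries with Xist alone it was at 0.28 (camera adjusted p = 2.84e-11). That fit kept cKO 1 and 3, whose pairs differed by 0.29 and 0.40, against 0.00 and 0.27 in pairs 4 and 5. These values argue against the mere presence of Xist as the whole cause. For the reason given for the gliosis list, they do not exclude unequal sex. A stronger hypoxia response of cKO Müller cells is a hypothesis that was not tested. A difference in how short of oxygen the sampled retinas were stays open too, since no measure of it is among the values.

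Other splits of the 8 libraries into 4 and 4 gave as many genes at an unadjusted p under 0.05 (1310) in 5 of 35, the real split included, so chance is not excluded. The highest other was 3343, and the split of numbers 1 and 3 against 4 and 5 gave 2554, which points to a structure of the samples by replicate number. Across genes, which are not independent, the cKO difference had a correlation of −0.60 with the contrast of numbers 1 and 3 against 4 and 5 within the groups, so the difference between the groups lies partly along this structure. Among the 8 splits that part the 4 pairs, as the real one does, the highest other was 197. A count of 0 genes past the threshold, as found, is reached by any split (35 of 35, with a highest other of 1), so the splits do not test it. With the block the real split gave 1305 genes and the highest other 1, and 8 splits are too few for a share under 0.05. As many process lists (10) passed in 11 of 35 splits, with a highest other of 14, and as many marker lists (4) in 4 of 35, with a highest other of 5, so chance is not excluded for either count.

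Of 400 groups of 4 values tested for a single value far from the other 3, 34 held one, where chance gives about 20. In WT 1 these were Lrtm1 (70.4 FPKM, above the others), Sema6a (22.9, below) and Pdgfra (18.4, below). In WT 3 they were Ugdh (21.5, below) and Fdft1 (15.98, above). In WT 4 they were Pgf (3.47), Atf5 (50.3) and Herpud1 (28.1), all above. In WT 5 they were Vegfa (171, below), mt-Cytb (91.8, below), mt-Nd6 (145, below), Cldn7 (5.04, below) and Klhl14 (2.31, above). In cKO 1 it was Idh1 (35.5, below). In cKO 3 they were Taldo1 (111), Ndufb8 (118), Rpl18 (209.9) and Cabp5 (182), all below, and Stat2 (11.9) and Stc2 (15.7), both above. In cKO 4 they were Timp2 (128) and Herpud1 (38.1), both above. In cKO 5 they were Slc16a3 (109, above) and mt-Nd2 (35.4, below).

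Means of lists also stood apart from the other 3 libraries of a group. WT 4 was above the other WT libraries for the HIF list (6.53 log2), pro-angiogenic factors (4.01), the ATF4 list (4.25), immediate early genes (4.40) and endothelial markers (5.18). cKO 4 was above the other cKO libraries for Nrf2 detoxification targets (5.23) and Müller cell identity (7.98). cKO 3 was above them for cholesterol synthesis (4.39) and the cell cycle (3.25), and below them for the nuclear-encoded respiratory chain (6.80).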

How the results depend on the processing

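The minimum of 5 FPKM, the covariates, the Xist libraries alone, the length and GC correction and the block with any other setting were chosen after the result was seen. The planned minimum means removed no gene, so they test nothing. The unblocked count of 0 genes held with both pseudocounts, each scaling, both eBayes settings, a threshold of 0.1, both covariates, the length and GC correction, a minimum of 5 FPKM and without any 1 library. It was 1 with library weights (lower) and 1 with the Xist libraries alone (Lcn2, higher). Of 168 named genes other than Nfe2l2, 70 passed with the block and 98 did not. The number of fragments is not given, and no counting error of low values was computed.

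With the block 1305 genes passed, and Nfe2l2 differed by −0.50 with an exact sign-flip p of 0.125, the smallest that 4 pairs allow. The block gave 402, 606, 524 and 821 genes without pair 1, 3, 4 or 5, and 839 with the Xist libraries alone, and the cause was not tested. The 839 rest on pairs 1 and 3, since WT 4 and 5 have no partner in that fit. With 10 other settings the count of the block stayed between 880 and 1337, with 130 to 408 genes higher and 680 to 1068 lower. The fewest higher were with eBayes without a trend (130) and the length and GC correction (238). Process lists past the threshold numbered 9 to 14 and marker lists 2 (with the Xist covariate) to 5 with the other settings and without any 1 library. An estimated correlation, above the preset one for 23 of 24 process and 7 of 7 marker lists, left 0 process and 0 marker lists. Without the block fry called 0 and 0, and with it 1 and 3, and the cause was not tested. With the Xist libraries alone Nfe2l2 differed by −0.39 (exact permutation p = 0.0667, the smallest of so few libraries), and with the Xist covariate by −0.38 (p = 0.0710).

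These values changed sign, or the list's test did, and all lay on the same side of the threshold as before unless stated, and the cause was not tested. With TPM scaling Idh1 was −0.012, the detoxification list −0.0073 and the cell cycle list −0.016. With quantile scaling the rod list was −0.016, the matrix list 0.018, the endothelial list 0.046 and Tkt −0.0079. With library weights Müller cell identity was 0.000333, cholesterol −0.011, Pgd 0.022, Idh1 −0.012 and Mfap5 −0.18. With a minimum of 5 FPKM the Nrf2 regulators were −0.082, the cell cycle list −0.052 and the cone list −0.097. With the unspliced-RNA covariate the lists were −0.052 (detoxification), −0.042 (NADPH supply), −0.023 (respiratory chain, no longer past the threshold), −0.0095 (ribosomal proteins, no longer past it), 0.17 (matrix) and 0.068 (cones). The genes were −0.10 (Keap1), −0.025 (Rpl22), 0.12 (Vegfa), −0.012 (Gpx4), −0.038 (Gstp1), −0.049 (Taldo1), −0.025 (Pgls), −0.034 (Idh1), 0.020 (Sema3f), 0.13 (Stat2) and 0.15 (Vtn). With the Xist covariate the lists were −0.023 (glutathione), −0.096 (detoxification), −0.071 (NADPH supply), −0.096 (respiratory chain), −0.091 (ribosomal proteins), 0.23 (matrix, now past the threshold), 0.14 (cones) and −0.036 (endothelial), and the genes −0.15 (Keap1), −0.050 (Rpl22), 0.17 (Vegfa), 0.12 (Mafg), −0.12 (Gpx4), −0.14 (Gstp1), −0.11 (Taldo1), −0.069 (Pgls), −0.023 (Idh1), 0.14 (Sema3f), −0.0075 (Timp2), 0.31 (Stat2), −0.0026 (Ndufb5), 0.013 (Guca1a), −0.000443 (Esam) and 0.17 (Vtn). With the Xist libraries alone the lists were −0.043 (detoxification), 0.13 (matrix), 0.018 (cones) and 0.012 (endothelial), and the genes −0.044 (Keap1), 0.10 (Vegfa), −0.040 (Idh1) and 0.029 (Vtn). With the length and GC correction they were −0.037 (detoxification), 0.047 (matrix), −0.0031 (cell cycle), −0.053 (Idh1), 0.021 (Sema6a) and 0.026 (Flt1).

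Leaving out 1 library moved Nfe2l2 between −0.59 and −0.38. The exact permutation p was 0.0571 without any 1 WT library, which is not the smallest allowed. It was 0.0286, the smallest allowed, without any 1 cKO library. The lists that changed sign, or of which only the test did (cones and anti-angiogenic), ranged from −0.040 to 0.11 (detoxification), −0.000685 to 0.099 (NADPH supply), −0.0042 to 0.069 (Nrf2 regulators), −0.013 to 0.17 (NF-kB), −0.040 to 0.065 (cell cycle), −0.071 to 0.31 (interferon), −0.045 to 0.12 (cholesterol), −0.24 to −0.077 (cones), −0.030 to 0.14 (endothelial), −0.16 to 0.058 (Müller cell identity), −0.015 to 0.17 (rods), −0.091 to −0.028 (anti-angiogenic) and −0.17 to 0.089 (matrix). The genes ranged from −0.022 to 0.11 (Keap1), −0.0049 to 0.15 (Pgls), −0.0039 to 0.10 (Tkt), −0.067 to 0.088 (Idh1), −0.24 to 0.091 (Vtn), −0.19 to 0.054 (Flt1), −0.11 to 0.0099 (Pgd) and −0.22 to 0.019 (Vegfa), and the cause was not tested.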

Other observations

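The long noncoding RNA Meg3 fell from 169 ± 92.3 to 82.0 ± 49.1 FPKM (−1.06; SD, n = 4, adjusted p = 0.469, and 0.00162 with the block), Malat1 from 896 ± 528 to 584 ± 379 (−0.69; 0.656 and 0.00491), and Miat from 7.57 ± 4.07 to 4.09 ± 2.20 (−0.77; 0.490 and 0.0211). Each was lower in all 4 pairs. These 3 genes were chosen after their values were seen.

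Lists with fewer than 5 measured members were not tested as lists, and their members were tested singly. Of the pericyte and smooth muscle markers, Rgs5 rose with the block (0.76, adjusted p = 0.00277), while Tagln differed by 0.56 (0.0742), Pdgfrb by −0.25 (0.183) and Vtn by −0.03 (0.896). Of the horizontal cell markers, Tfap2b fell with the block (−0.63, adjusted p = 0.00794), and Sept4 (−0.17, adjusted p = 0.182) and Tpm3 (−0.11, adjusted p = 0.486) did not pass. The NADPH oxidase subunits Cyba (0.19, adjusted p = 0.498) and Rac1 (0.15, adjusted p = 0.229) did not pass. Neither did the pigment epithelium markers Ttr (0.08, adjusted p = 0.745) and Rdh5 (0.14, adjusted p = 0.758), the lens marker Bfsp2 (−0.42, adjusted p = 0.122) or the erythroid marker Hbb-bs (0.47, adjusted p = 0.263). The fibroblast markers Col1a2 (0.21, adjusted p = 0.198), Pdgfra (0.15, adjusted p = 0.266) and Mfap5 (0.65, adjusted p = 0.415) did not pass either. Without the block none of these members passed.

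Xist, which female cells express, was at 58.1, 72.1, 39.9 and 27.0 FPKM in WT 1, 3, 4 and 5, and at 25.01, 50.004, 0.0863 and 0.00505 in cKO 1, 3, 4 and 5 (adjusted p = 0.469, and 0.0533 with the block). No Y-linked gene was in the table. Only genes with a mean FPKM above 2 over the 8 libraries were in it, so this absence does not tell the sex of any library.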
